A study of Mus musculus with 12 samples.

How the data were processed

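RNA sequencing values of 10 libraries were analysed, 3 WT, 3 GSH, 3 Cas9 and 1 Ctrl, of the 12 samples that the labels describe; the other 2, Ctrl 1 and Ctrl 2, were not analysed here. Per the labels' protocols, 4T1 cells were grown in DMEM with serum, RNA was extracted with Trizol, and libraries were made with the NEBNext Ultra RNA kit, and the design text names a HiSeq instrument. The submitters' processing notes name Bowtie2 (2.2.3), HISAT2 (2) and HTSeq (0.6.0) and the build mm8, without saying what each was used for. Some gene identifiers in the WT and GSH table are younger than that build, so no coordinates are given. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

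Neither the labels nor the file headers state a unit. The deposited values were taken as FPKM, fragments per kilobase of transcript scaled to the mapped reads, from the values themselves. The authors' normalization divides by a library total, and the WT and GSH libraries and the Ctrl and Cas9 libraries were tabulated separately, over 30803 Ensembl identifiers and 17558 symbols, so tests were made within each table only. Symbols for the Ensembl identifiers were taken from the reference tables, which matched 30190 of them. A gene's FPKM values move in whole multiples of what 1 read is worth. Whole reads could therefore be recovered for 99.2% of the WT and GSH genes above 0 and for 94.57% of the Ctrl and Cas9 genes above 0, taking values within at most 0.15 read of a whole number. For the WT and GSH table, the merged exon lengths of GENCODE M21 gave a single library total for 96.4% of 17525 genes (within a relative 1e-05). For the Ctrl and Cas9 table they did so for 1.9%. Lengths entered there for few genes, with 24 raised to a higher common multiple of reads and 103 read by length. Recovered reads served for depth, for thinning, for an added test and for RPM, which are recovered reads scaled to the library total. Depth was 18530125 to 30166552 reads in WT and GSH libraries and 33287050 to 39259895 in Ctrl and Cas9 libraries.

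The design fixed before the data were examined named a count model for count files and, for normalised values, limma on log2(value + 1). As the files held FPKM and not counts, the latter was used: lmFit and eBayes with a trend in limma 3.58.1 (R 4.3.3), a pseudocount of 1, group as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05 over genes with a mean FPKM of 1 or more over the libraries compared. That minimum was chosen once the unit was known. This left 12283 genes for GSH against WT and 11407 for Cas9 against Ctrl. Fold changes are on the log2(FPKM + 1) scale. Because the Ctrl group has 1 library, that fit has 2 residual degrees of freedom, all from the Cas9 libraries.

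Gene lists (48, fixed before the data were examined, covering pathways, stress responses and markers of other cell types) were tested on the same log2 values with camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated per list, over lists with 5 or more tested genes, with Benjamini-Hochberg adjustment over the lists; fry was run beside it. Counts "adjusted over the list alone" use an adjustment within the list. List medians were also placed among 10000 random lists of the same size drawn within 20 bins of mean expression. Members of a random list were drawn independently, so the percentiles take no account of correlation between genes. Genes were named by a rule fixed in advance. It took the 10 largest increases and 10 largest decreases among genes past the threshold without overlap between groups and with a higher group mean of 5 or more (FPKM in place of the CPM first written), leaving out genes without a symbol, predicted Gm genes, Rik clones and pseudogenes; the 4 members with the smallest p of each called list; and the 2 with the smallest p of the glutathione, NRF2, p53 and interferon lists. The first part named no gene for Cas9 against Ctrl, and not every gene named by the second part is printed or drawn; some are not reported here.

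The tests were checked on simulated libraries with the real genes' mean reads and library totals and 200 changed genes. For GSH against WT, over 12186 genes, 35 of 50 genes changed by 1.25-fold, 45 of 50 by 1.5-fold, 48 of 50 by 2-fold and 48 of 50 by 4-fold were called in the right direction, with 9 unchanged genes called. For Cas9 against Ctrl, over 11342 genes, 1, 9, 44 and 45 of 50 were called at these sizes, with 4 unchanged genes called. A list of genes raised by 1.5-fold was called in both simulations and 0 of 50 unchanged lists were. Genes were simulated independently, so this says nothing of false list calls among correlated genes. All genes of a simulation had the same relative spread beyond counting error, unlike real genes. The shares found therefore do not measure power in the real libraries, and missing calls there do not show absent changes. In the real libraries the other splits of WT and GSH called 3 to 10 lists, and singling out each Cas9 library called 14 to 16.

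The mean chi-square per gene between libraries of the same group was 3.3 to 7.18 in WT and GSH and 56.8 to 118 in Cas9. Counting error alone gives a mean of about 1. The median was lower, 0.733 to 1.05 in WT and GSH and 7.28 to 16.5 in Cas9. Counting error alone gives a median well below its mean, so these medians are not to be read against 1. Each library was counted as a separate sample, although such spread does not show separate cultures. Alternatives set before the data were examined were relative log expression and upper-quartile scaling, no filter and a stricter one, a fold threshold, thinning, another pseudocount, leaving out each library, a replicate block, a pooled spread and an estimated correlation. Alternatives added after seeing the data were limma's voom on recovered reads, leaving out or keeping only WT 3, GSH 2 and GSH 3, a term for those libraries, rescaling without mitochondrially encoded genes, and removing a trend on GC content and length with values for 99% of tested genes. Marker lists added after seeing the data covered secretory gland families, nasal mucosa, salivary gland, cornified epidermis, skeletal muscle, haemoglobin and cytotoxic granule genes.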

Results

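Messenger RNA was sequenced from samples labelled as 4T1, a mammary carcinoma cell line derived from a BALB/c mouse. The labels describe 12 samples in 4 groups named by genotype (WT, GSH, Ctrl and Cas9) with 3 samples each, and the design text sets GSH beside WT and Cas9 beside Ctrl. Values of 10 samples were used, which were 3 WT, 3 GSH, 3 Cas9 and 1 Ctrl library (Ctrl 3); Ctrl 1 and Ctrl 2 were not analysed here. The labels do not expand GSH and name no gene targeted with Cas9, so the targeted gene could not be read out first. The growth protocol in the labels describes cells in culture for each group, whereas the Ctrl and Cas9 libraries held leukocyte transcripts that carcinoma cells in culture are not known for.

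The WT and GSH libraries shared one gene table of 30803 Ensembl genes, and the Ctrl and Cas9 libraries another of 17558 gene symbols. Whole reads, recovered from the steps of the FPKM values, summed to 21952117, 20295614 and 21445679 in WT 1 to 3 and to 30166552, 18890926 and 18530125 in GSH 1 to 3. Ctrl 3 held 39259895 reads, and Cas9 1 to 3 held 35980666, 33287050 and 34886311 reads. The 10 most abundant genes took 22.29 to 23% of all FPKM in the WT libraries, 18.19 to 18.52% in the GSH libraries and 8.48 to 9.44% in the Ctrl and Cas9 libraries. The 2 tables also differed in a leukocyte transcript. Ptprc, the pan-leukocyte surface phosphatase CD45, stood at 0.319 to 0.746 RPM (recovered reads scaled to the library total) in the WT and GSH libraries. In the Ctrl and Cas9 libraries, which were normalised as a separate table, it stood at 92.8 to 124 RPM.

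GSH cells differed from WT cells by small, closely replicated shifts in many transcripts. More genes fell than rose among transcripts of the mitochondrial genome, endoplasmic reticulum chaperones and MHC class I presentation. More rose than fell among immediate early genes, ribosome genes and genes of the thioredoxin, NADPH and NRF2 systems. These lists were called with a preset correlation between genes and none with an estimated one (smallest adjusted p = 0.343), and many members did not pass. A list of histone genes fixed as a sign of poly(A) selection had 3 tested members. The replication-dependent Hist1h1c and Hist1h2bc, named after their values were seen, passed (median log2 change 0.38), with medians of 0.34, 0.44 and 0.37 in GSH 1 to 3 and -0.01, -0.03 and 0.04 in WT 1 to 3. The third, H1f0, rose as well (log2 change 0.34) but is replication-independent and so no such sign. The list was too small for camera, and the 16 members below the filter together took 2.1 to 2.61 RPM in WT and 2.32 to 2.81 RPM in GSH. Egr1 (ENSMUSG00000038418), an immediate early zinc-finger transcription factor, rose from 2.31 ± 0.205 FPKM in WT to 10.7 ± 2.49 FPKM in GSH (SD, n = 3 each; log2 change 1.80, SE 0.14, adjusted p = 0.00162). Rsrp1 (ENSMUSG00000037266), an arginine/serine-rich protein gene, fell from 94.4 ± 1.92 to 49 ± 0.964 FPKM (log2 change -0.93, SE 0.03, adjusted p = 0.000182). Neat1 (ENSMUSG00000092274), the long noncoding RNA of nuclear paraspeckles, fell from 87.1 ± 1.4 to 50.8 ± 0.626 FPKM (log2 change -0.77, SE 0.03, adjusted p = 0.000182). Fold changes throughout are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes.

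In limma's moderated test, 4547 of 12283 tested genes (37%) passed a Benjamini-Hochberg adjusted p of 0.05, 2533 higher and 2014 lower in GSH. The median absolute log2 change among them was 0.22, and 2 higher and 12 lower genes exceeded a log2 change of 1. At an unadjusted p of 0.05, 5881 genes passed. The 3 WT and 3 GSH libraries did not overlap for 52.5% of tested genes, where chance alone gives 10%. Of the genes that passed, 55.7% were higher in GSH. Mitochondrially encoded genes took 8.17 to 8.48% of reads in WT and 5.72 to 6.1% in GSH, and with FPKM rescaled to the total without them, 42.9% of 4403 called genes were higher. In limma's test against a fold change of 1.5, 0 genes passed, with 27 at an unadjusted p of 0.05, and without WT 1 the count over any fold was 2998. Odorant-binding protein, major urinary protein and related secretory genes stood at 344 to 471 RPM in WT 3, GSH 2 and GSH 3 and at 3.46 to 31.8 RPM in the other 3 libraries. In limma, 0 genes passed within WT 3, GSH 2 and GSH 3 (3435 at an unadjusted p of 0.05), and 4 passed within the other 3 libraries (3797 unadjusted). Each of these fits has 1 library in one group and little power, so the low counts say little about stability. Between these sets of libraries the sign was the same for 77.6% of all tested genes and for the 4547 called over the 6 libraries, which their selection favours.

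Several of the largest increases were genes induced early after stimulation. Jun, a subunit of the AP-1 transcription factor, rose from 14.6 ± 0.793 to 24.7 ± 1.96 FPKM (SD, n = 3 each), and Ier2 rose from 27.8 ± 1.99 to 42.2 ± 1.42 FPKM. Klf6, a Krüppel-like transcription factor, rose from 28.7 ± 0.653 to 47.3 ± 2.26 FPKM. Rhob, a small GTPase, rose from 32.3 ± 1.03 to 63.5 ± 5.03 FPKM, and Rgs16, a regulator of G-protein signalling, from 35.3 ± 0.486 to 52.8 ± 1.21 FPKM. Csf2, which encodes the cytokine GM-CSF, rose from 4.53 ± 0.032 to 8.27 ± 0.72 FPKM. Tuba1c, an alpha-tubulin, rose from 63.4 ± 4.49 to 94.2 ± 4.7 FPKM. The microRNA gene Mir3091 (log2 change 0.85) and the clone-named gene AC122453.1 (log2 change 0.53) completed the 10 largest increases. Adjusted p values of these genes lay between 0.000909 for Rgs16 and 0.00427 for Mir3091.

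Among the 10 largest decreases, mt-Co3 and mt-Co2, which encode subunits of cytochrome c oxidase, fell by 1.18 (SE 0.18) and 1.12 (SE 0.29) on the log2 scale, and the mitochondrial transfer RNA gene mt-Ty fell by 1.12 (SE 0.15). Ccnb1ip1, a cyclin B1-interacting protein gene, fell from 55.2 ± 2.34 to 29.3 ± 0.823 FPKM (SD, n = 3 each). Vamp2, a synaptobrevin of vesicle fusion, fell from 21 ± 1.01 to 11.9 ± 0.216 FPKM. The noncoding RNA gene Hotairm1, which lies in the Hoxa cluster, fell by 0.77 (SE 0.19), the microRNA gene Mir221 by 0.81 (SE 0.19) and the clone-named gene AC122119.2 by 1.96 (SE 0.35) on the log2 scale. Adjusted p values were 0.0249 for mt-Co2, 0.0193 for Mir221 and 0.0233 for Hotairm1. Calls of these 3 genes ended when 1 library was left out and with no filter (adjusted p = 0.0932, 0.0645 and 0.0751). For mt-Co2 this held without WT 1 (adjusted p = 0.0747), WT 2 (0.0725), GSH 1 (0.0608) or GSH 2 (0.0663). For Mir221 it held without WT 1 (0.0542) or GSH 2 (0.0592), and for Hotairm1 without WT 1 (0.0749), WT 3 (0.0674), GSH 2 (0.0612) or GSH 3 (0.0631). The replicate block also ended the call of mt-Co2 (limma adjusted p = 0.0585), and voom that of Mir221 (0.0507). A term for WT 3, GSH 2 and GSH 3 ended that of Hotairm1 (0.0534). Over all alternatives their adjusted p ran from 0.00238, 0.0112 and 0.0077 to 1. Reads of short genes inside longer transcripts, and of mitochondrial genes with nuclear copies, could not be told from those of their hosts or copies in the deposited values.

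**Figure D1:**
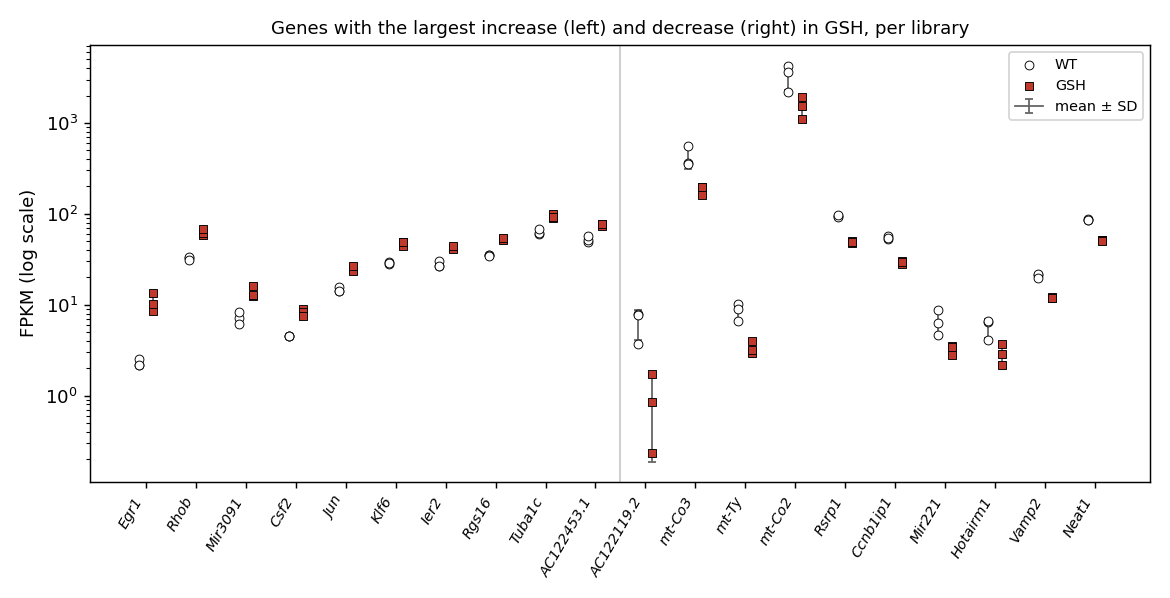
FPKM (log axis) of the 10 genes with the largest increase, left of the vertical line, and the 10 with the largest decrease in GSH against WT. Each point is 1 library (open circles WT, red squares GSH) and grey bars give the mean ± SD of 3 libraries; the groups do not overlap for any of the 20 genes, and Egr1 stands at 2.31 FPKM in WT and 10.7 FPKM in GSH.

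The 13 protein-coding transcripts of the mitochondrial genome had a median log2 change of -0.46, and 9 of them fell, 0 rose and 4 did not pass (10 fell when adjusted over the list alone). The camera test of the list gave an adjusted p of 4.73e-06 with the preset correlation and an adjusted p = 0.492 with an estimated correlation. Cytochrome c oxidase subunit mt-Co1 fell from 19331 ± 265 to 13530 ± 157 FPKM, mt-Cytb from 16398 ± 159 to 11488 ± 121 FPKM, mt-Nd1 from 14242 ± 228 to 10304 ± 548 FPKM and mt-Nd4 from 3137 ± 82.7 to 2344 ± 84.1 FPKM (SD, n = 3 each). With no filter the calls of mt-Co1 (adjusted p = 0.681), mt-Cytb (0.633), mt-Nd1 (0.627) and mt-Nd4 (0.119) ended. Of 59 tested nuclear-encoded genes of oxidative phosphorylation, 23 rose, 2 fell and 34 did not pass (24 and 2 adjusted over the list alone). The camera test gave an adjusted p of 0.003, and an adjusted p = 0.765 with an estimated correlation. Ndufa8, of respiratory complex I, rose from 44.6 ± 1.89 to 59.3 ± 0.983 FPKM, Atp5a1, of ATP synthase, from 130 ± 3.65 to 168 ± 5.87 FPKM, Atp5d from 72.3 ± 1.11 to 91.6 ± 2.51 FPKM, and Sdhc, of complex II, from 14.8 ± 0.544 to 18.2 ± 0.249 FPKM. The call of this list ended without WT 2 (adjusted p = 0.0731) and within WT 3, GSH 2 and GSH 3 alone (adjusted p = 0.482), a fit with 1 WT library that kept the calls of 10 lists.

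More genes of the translation machinery were higher than lower in GSH. Of 67 cytosolic ribosomal protein genes, 31 rose, 3 fell and 33 did not pass (40 and 3 adjusted over the list alone), with a median log2 change of 0.19, a camera adjusted p of 4.73e-06 and an adjusted p = 0.688 with an estimated correlation. Rpsa rose from 349 ± 23.4 to 451 ± 11.3 FPKM, Rpl8 from 443 ± 19.1 to 563 ± 18.6 FPKM, Rpl15 from 130 ± 6.38 to 162 ± 4.31 FPKM and Rpl5 from 192 ± 5.64 to 228 ± 3.09 FPKM (SD, n = 3 each), although ribosomal protein genes share reads with many processed pseudogenes and their levels are uncertain to that degree. Of 37 tested MYC and ribosome biogenesis genes, 24 rose, 2 fell and 11 did not pass (25 and 2 adjusted over the list alone). Their camera adjusted p was 4.17e-05, with an adjusted p = 0.343 with an estimated correlation. Odc1, the first enzyme of polyamine synthesis, rose from 98 ± 4.06 to 132 ± 3.11 FPKM, and the nucleolar genes Fbl, Pes1 and Rrs1 had log2 changes of 0.27, 0.26 and 0.22 (SE 0.03 each).

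Among genes of redox defence and NADPH supply, too, more rose than fell. Of 30 tested NRF2 target genes, 16 rose, 1 fell (Ephx1) and 13 did not pass (16 and 1 adjusted over the list alone). The camera test gave an adjusted p of 0.000437, and an adjusted p = 0.343 with an estimated correlation. Gsr, which reduces oxidised glutathione, rose from 24.6 ± 0.273 to 30.1 ± 0.508 FPKM, the autophagy receptor Sqstm1 from 85.4 ± 1.54 to 101 ± 1.59 FPKM and the ferritin heavy chain gene Fth1 from 446 ± 8.32 to 523 ± 4.17 FPKM (SD, n = 3 each). Of 23 tested thioredoxin, peroxiredoxin and dismutase genes, 16 rose, 0 fell and 7 did not pass (17 and 0 adjusted over the list alone). The camera test gave an adjusted p of 0.000412, and an adjusted p = 0.492 with an estimated correlation. Mitochondrial peroxiredoxin Prdx3 rose from 51.7 ± 1.12 to 62.8 ± 0.63 FPKM, catalase (Cat) from 9.38 ± 0.137 to 11.7 ± 0.322 FPKM, mitochondrial superoxide dismutase Sod2 from 7 ± 0.154 to 8.59 ± 0.307 FPKM, and thioredoxin reductase Txnrd1 from 31.3 ± 0.596 to 36 ± 0.481 FPKM. Among 21 tested genes of the pentose phosphate pathway and NADPH supply, 16 rose, 1 fell and 4 did not pass (17 and 1 adjusted over the list alone). That list had a camera adjusted p of 0.000285 and an adjusted p = 0.492 with an estimated correlation. G6pdx, the entry enzyme of the pathway, rose from 28.2 ± 1.05 to 35.4 ± 1.48 FPKM, Phgdh, of serine synthesis, from 109 ± 8.23 to 138 ± 5.57 FPKM, Mthfd1, of folate metabolism, from 35.8 ± 0.436 to 42.2 ± 0.729 FPKM, and malic enzyme Me2 from 5.39 ± 0.214 to 6.67 ± 0.186 FPKM.

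The list of genes for glutathione synthesis and use was not called (camera adjusted p = 0.434). Of its 33 tested members, 8 rose, 4 fell and 21 did not pass (10 and 4 adjusted over the list alone). Its 2 members with the smallest p moved in opposite directions, as Gsr rose (log2 change 0.28) and Mat2a, which makes S-adenosylmethionine, fell from 93.1 ± 1.03 to 74.8 ± 1.43 FPKM (SD, n = 3 each).

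Of 24 tested heat shock response genes, 14 rose, 0 fell and 10 did not pass (14 and 1 adjusted over the list alone). The camera test gave an adjusted p of 0.003, and an adjusted p = 0.492 with an estimated correlation. Hsp90ab1, a cytosolic HSP90, rose from 959 ± 19.7 to 1206 ± 21.8 FPKM, Hspa8 from 336 ± 7.27 to 406 ± 8.96 FPKM, and the HSP90 co-chaperones Fkbp4 and Stip1 had log2 changes of 0.39 (SE 0.02) and 0.21 (SE 0.03). In the list of the endoplasmic reticulum unfolded protein response, 21 of 35 tested members fell, 1 rose and 13 did not pass (22 and 1 adjusted over the list alone). The camera test gave an adjusted p of 4.73e-06, and an adjusted p = 0.492 with an estimated correlation. The luminal HSP90 gene Hsp90b1 fell from 274 ± 4.62 to 215 ± 4.82 FPKM, Hspa5, which encodes BiP, from 705 ± 6.91 to 603 ± 5.94 FPKM, and the protein disulfide isomerase genes Pdia3 and Pdia4 from 344 ± 11.4 to 268 ± 9.81 FPKM and from 112 ± 2.19 to 92.9 ± 0.638 FPKM (SD, n = 3 each). Of 23 tested genes of MHC class I presentation, 11 fell, 1 rose and 11 did not pass (11 and 1 adjusted over the list alone). The camera test gave an adjusted p of 0.00207, and an adjusted p = 0.343 with an estimated correlation. B2m, the light chain of class I molecules, fell from 677 ± 23.1 to 577 ± 7.01 FPKM and H2-Q4 from 50.5 ± 2.06 to 41.7 ± 1.05 FPKM, and Pdia3 and Calr, which also fold proteins in the endoplasmic reticulum, fell by 0.36 and 0.18 on the log2 scale. The call of Calr ended with no filter (adjusted p = 0.0619).

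Of 29 tested immediate early genes, 15 rose, 1 fell and 13 did not pass (16 and 1 adjusted over the list alone), with a median log2 change of 0.22, a camera adjusted p of 4.17e-05 and an adjusted p = 0.492 with an estimated correlation. Besides Egr1, Jun and Klf6, the list was led by Dusp5, a nuclear phosphatase of ERK, which rose from 13.5 ± 0.144 to 18.6 ± 0.692 FPKM (SD, n = 3 each). Cell cycle genes were called near the threshold. Of 42 tested G1/S genes 17 rose, 4 fell and 21 did not pass (17 and 5 adjusted over the list alone), and of 46 G2/M genes 23 rose, 7 fell and 16 did not pass (23 and 7 adjusted over the list alone). Both lists had a camera adjusted p of 0.0423, and adjusted p = 0.55 for G1/S and adjusted p = 0.688 for G2/M with an estimated correlation. Cyclin D1 (Ccnd1) rose from 112 ± 1.7 to 137 ± 2.61 FPKM, the replicative helicase genes Mcm6, Mcm3 and Mcm2 had log2 changes of 0.27, 0.29 and 0.35, and Cdk1, Cdc20, Ccnb1 and Ube2c had log2 changes of 0.23, 0.23, 0.22 and 0.33. Both calls ended with relative log expression scaling, at adjusted p = 0.0545 for G1/S and 0.0716 for G2/M. The G1/S call also ended without WT 1 (adjusted p = 0.0691), WT 2 (0.0508), GSH 1 (0.0778) or GSH 2 (0.0523). The G2/M call ended without WT 2 (adjusted p = 0.0731) or GSH 1 (0.138), and within WT 3, GSH 2 and GSH 3 alone, with 1 WT library, both lists had an adjusted p of 0.213.

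The p53 target list and the interferon-stimulated list were not called (camera adjusted p = 0.952 and 0.247). Of 31 tested p53 targets, 5 rose and 6 fell (5 and 6 adjusted over the list alone), among them Psrc1, which fell from 3.84 ± 0.059 to 2.87 ± 0.122 FPKM (SD, n = 3 each). Of 23 tested interferon-stimulated genes, 1 rose and 5 fell (1 and 3 adjusted over the list alone). Trim25 rose from 14.1 ± 0.238 to 16.6 ± 0.212 FPKM, and the transcription factor gene Irf1 fell from 9.52 ± 0.213 to 6.98 ± 0.502 FPKM. In all, 13 of 42 tested lists were called, 10 up and 3 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.343. The median, mean and test differed in sign for 7 lists, of which 0 were called. The rotation test fry asks whether a list's genes move one way on balance. For the 13 called lists, the rotation test fry gave unadjusted p between 7.18e-05 (NRF2 targets) and 0.0304 (oxidative phosphorylation). For lists not called, the rotation test fry gave unadjusted p between 0.000197 (ferroptosis and iron handling) and 0.722 (cytosolic nucleic acid sensing). Small values from fry were therefore not confined to the called lists and add no separate support to those calls. Among 10000 random lists matched on expression, the medians of the 3 lists called down lay at percentiles 0 to 0.1. Those of the 10 called up lay at 89.6 to 100, lowest for oxidative phosphorylation (89.6) and G2/M genes (90.2). The random lists carry no correlation between genes, so these percentiles share the limit of the preset correlation.

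**Figure D2:**
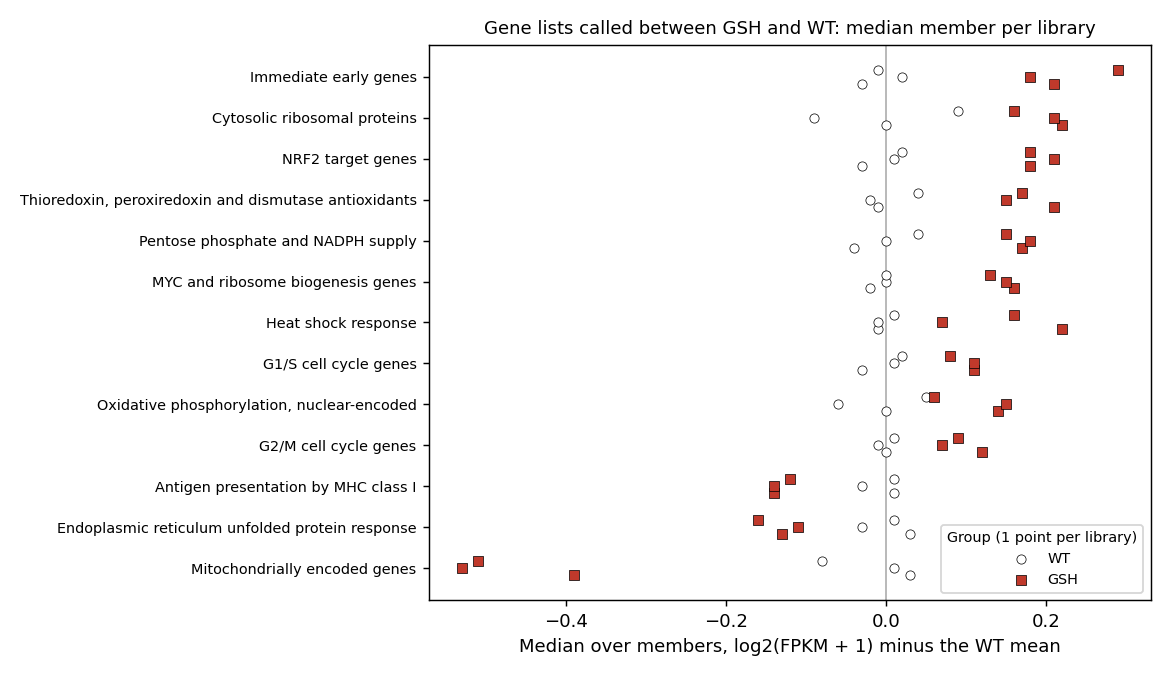
Median over the tested members of each of the 13 called lists, as log2(FPKM + 1) minus the WT mean, with 1 point per library (open circles WT, red squares GSH; replicates 1 to 3 are offset from bottom to top in each row). The mitochondrially encoded list lies lowest in GSH, and the 3 GSH points lie on one side of the 3 WT points in each row, where the list medians over genes range from -0.46 to 0.22.

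Cas9 libraries had higher levels than Ctrl 3 of interferon-stimulated genes, MHC class I genes and lymphocyte markers, and lower levels of macrophage and adipocyte markers. These statements rest on lists, since no single gene passed, and with an estimated correlation none of these lists was called (adjusted p = 0.184 for interferon-stimulated genes and 0.736 to 0.789 for the others). Igtp, an interferon-inducible GTPase, stood at 65.4 FPKM in Ctrl 3 and at 125 ± 13.9 FPKM in the Cas9 libraries (SD, n = 3). H2-T23, a nonclassical class I gene, stood at 184 FPKM in Ctrl 3 and 300 ± 3.89 FPKM in Cas9. As the Ctrl group entered with 1 library, the spread came from the Cas9 libraries alone and Ctrl 3 was assumed to vary like them, which holds for each result of this comparison. Transcripts of other cell types also differed between these libraries, such as cornified epidermis genes at 1239 RPM in Cas9 3 and 146 RPM in Ctrl 3. Each list difference may therefore follow the mix of cells and not expression within cells, which was not tested.

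In limma, 0 of 11407 tested genes passed an adjusted p of 0.05, 210 had an unadjusted p below 0.05, and the smallest adjusted p was 1. With voom weights on recovered reads, 0 genes passed as well, with 189 at an unadjusted p of 0.05. With the spread pooled over all 10 libraries, on genes shared by symbol, 43 genes passed, 30 higher and 13 lower in Cas9. That fit assumes that the Ctrl and Cas9 libraries vary like the WT and GSH libraries. Pairs of Cas9 libraries differed by a mean chi-square per gene of 56.8 to 118 and pairs within WT or GSH by 3.3 to 7.18. That assumption therefore did not hold, and the genes that passed in the pooled fit are not relied on. Ctrl 3 lay outside the range of the 3 Cas9 libraries for 42.6% of tested genes, which is common by chance with 1 library against 3. Cas9 3 stood apart on the first principal component (63% of the variance). Cornified epidermis genes stood at 1239 RPM in Cas9 3, 79.9 RPM in Cas9 1, 139 RPM in Cas9 2 and 146 RPM in Ctrl 3.

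Of 53 tested interferon-stimulated genes, 52 had a positive log2 difference, with a median of 0.43, and 15 were higher when adjusted over the list alone, while 0 passed over all genes. The camera adjusted p of this list was 1.37e-35 with the preset correlation, and adjusted p = 0.184 with an estimated correlation. Its median lay at percentile 100 of 10000 random lists matched on expression, and fry gave an unadjusted p of 0.00122. The list medians of Cas9 1, 2 and 3 above Ctrl 3 were 0.41, 0.38 and 0.39. Usp18, which removes ISG15 from proteins, stood at 15.8 FPKM in Ctrl 3 and 28.1 ± 2.37 FPKM in Cas9 (SD, n = 3), and the interferon-inducible Rtp4 at 14.4 and 25 ± 2.37 FPKM. The 25 tested genes of MHC class I presentation all had positive differences (median 0.28; camera adjusted p = 3.72e-14; adjusted p = 0.736 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. H2-T22 stood at 50.5 FPKM in Ctrl 3 and 84.7 ± 9.28 FPKM in Cas9, H2-Q7 at 10.1 and 20 ± 3.99 FPKM, and the immunoproteasome gene Psmb9 at 95.9 and 133 ± 5.78 FPKM. Class I genes resemble each other closely, so the split of reads among the H2 genes is uncertain.

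Markers of immune and stromal cells differed between Ctrl 3 and the Cas9 libraries in both directions. Lymphocyte markers were higher (11 of 12 tested members positive, median 0.83, camera adjusted p = 4.4e-10, adjusted p = 0.736 with an estimated correlation), with list medians of 0.85, 0.81 and 0.45 in Cas9 1 to 3. The T-cell receptor complex gene Cd3g stood at 4.49 FPKM in Ctrl 3 and 9.4 ± 1.61 FPKM in Cas9 (SD, n = 3), Cd3e at 0.958 and 2.64 ± 0.656 FPKM, Cd8a at 1.69 and 3.82 ± 1.03 FPKM, and Cd2 at 1.16 and 2.21 ± 0.308 FPKM. Macrophage and myeloid markers were lower (18 of 21 negative, median -0.30, camera adjusted p = 0.00113, adjusted p = 0.789 with an estimated correlation), with list medians of -0.07, -0.13 and -0.77 in Cas9 1 to 3. Cx3cr1, a chemokine receptor, stood at 69.3 FPKM in Ctrl 3 and 37.1 ± 18.9 FPKM in Cas9, Adgre1 at 31.4 and 21.5 ± 4.96 FPKM, Itgam at 45.7 and 37.2 ± 5.34 FPKM, and Mrc1 at 63.5 and 51.8 ± 8.93 FPKM. Adipocyte markers were lower (6 of 7 negative, median -0.34, camera adjusted p = 0.000167, adjusted p = 0.789 with an estimated correlation). Cfd, which encodes adipsin, stood at 21.3 FPKM in Ctrl 3 and 2.1 ± 1.79 FPKM in Cas9, Adipoq at 2.98 and 0.991 ± 0.453 FPKM, Cidec at 4.16 and 1.67 ± 0.25 FPKM, and Cebpa at 22.5 and 18.7 ± 4.69 FPKM. Ptprc stood at 21.1 FPKM in Ctrl 3 and at 18.5, 21 and 15.9 FPKM in Cas9 1 to 3.

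**Figure D3:**
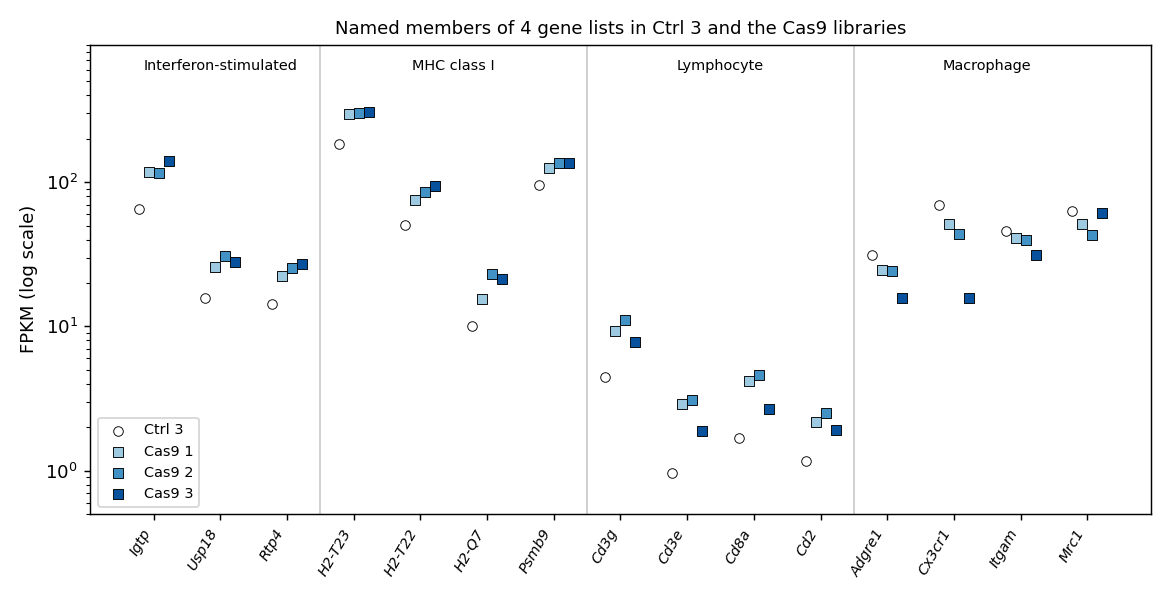
FPKM (log axis) of members with the smallest p in each of 4 lists, with 1 point per library (open circle Ctrl 3, blue squares Cas9 1 to 3). Each of the 15 genes has its 3 Cas9 points on one side of Ctrl 3, above it for the interferon-stimulated, MHC class I and lymphocyte genes and below it for the macrophage genes. The genes were chosen for small p, and 42.6% of all tested genes showed such separation.

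Cytosolic ribosomal protein genes were higher in Cas9 (64 of 67 positive, median 0.28, camera adjusted p = 1.78e-22, adjusted p = 0.789 with an estimated correlation), as shown by Rps3 at 595 FPKM in Ctrl 3 and 821 ± 103 FPKM in Cas9 (SD, n = 3), Rpl22 at 169 and 229 ± 27.3 FPKM, Rpl19 at 481 and 615 ± 38.4 FPKM, and Rpl11 at 370 and 481 ± 47.3 FPKM. Genes of nuclear-encoded oxidative phosphorylation had a median of 0.10 (48 of 59 positive, camera adjusted p = 0.000907, adjusted p = 0.789 with an estimated correlation), with Ndufc2 at 53.4 and 70.2 ± 9.45 FPKM and Cox7c at 181 and 231 ± 34.6 FPKM. Targets of ATF4, the transcription factor of the integrated stress response, were higher (28 of 34 positive, median 0.22, camera adjusted p = 2.44e-06, adjusted p = 0.789 with an estimated correlation). Atf3 stood at 4.95 and 10.4 ± 2.84 FPKM, Cebpg at 8.61 and 12 ± 0.877 FPKM, and the cystine transporter genes Slc7a11 and Slc3a2 at 2.62 and 6.46 ± 2.17 FPKM and at 13.7 and 18 ± 0.184 FPKM. The last pair also led the list of glutathione synthesis and use (29 of 40 positive, median 0.16, camera adjusted p = 0.000907, adjusted p = 0.789 with an estimated correlation), followed by Gclm, the modifier subunit of glutamate-cysteine ligase, at 10.3 and 15.4 ± 2.68 FPKM and Mgst1 at 32.6 and 44.9 ± 5.81 FPKM. NRF2 targets were not called (22 of 33 positive, camera adjusted p = 0.0765), nor were p53 targets (16 of 34 positive, camera adjusted p = 0.923), in which Cdkn1a stood at 16.6 and 21.3 ± 2.52 FPKM and Ak1 at 9.52 and 7.31 ± 0.975 FPKM.

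Glycolysis and hypoxia targets were higher (34 of 45 positive, median 0.21, camera adjusted p = 3.35e-06, adjusted p = 0.789 with an estimated correlation), with Pfkfb3, which makes the activator of phosphofructokinase, at 6.08 FPKM in Ctrl 3 and 9.83 ± 0.539 FPKM in Cas9 (SD, n = 3), Ankrd37 at 2.06 and 5.74 ± 1.33 FPKM, Nfil3 at 6.91 and 10.2 ± 0.0278 FPKM and Mxi1 at 11.3 and 18.4 ± 3.43 FPKM. The medians of that list in Cas9 1 to 3 were -0.02, 0.27 and 0.38, so Cas9 1 did not share the rise. Heat shock response genes were higher (21 of 25 positive, median 0.16, camera adjusted p = 6.94e-05, adjusted p = 0.789 with an estimated correlation), among them Hspa1b at 20.2 and 41.5 ± 13.8 FPKM, Cryab at 8.85 and 12.9 ± 0.115 FPKM and Hspb8 at 51.6 and 70.1 ± 5.14 FPKM. Epithelial junction and keratin genes had a median of 0.33 (32 of 38 positive, camera adjusted p = 3.35e-06, adjusted p = 0.789 with an estimated correlation), and their medians in Cas9 1 to 3 were 0.01, 0.18 and 0.74, highest in Cas9 3, where cornified epidermis genes were most abundant. The epithelial transcription factor gene Elf3 stood at 7.33 and 14.6 ± 1.32 FPKM, Rab25 at 18.9 and 32 ± 3.97 FPKM, Esrp2 at 4.86 and 7.99 ± 0.965 FPKM, and Ocln at 2.21 and 3.86 ± 0.572 FPKM.

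The remaining called lists each lost their call without 1 Cas9 library, besides oxidative phosphorylation, whose call ended without Cas9 3 (adjusted p = 0.0778). Without Cas9 1, the calls ended for cholesterol synthesis (median -0.24, camera adjusted p = 0.00144 with all libraries, 0.542 without), mesenchymal genes (median -0.17, 0.00301 and 0.407), collagens and matrix (median -0.22, 0.00393 and 0.219), endothelial markers (median 0.34, 0.00627 and 0.442) and fatty acid synthesis (median -0.08, 0.0268 and 0.464). Immediate early genes (median 0.15, camera adjusted p = 0.0218) lost their call without Cas9 2 (adjusted p = 0.132) or Cas9 3 (adjusted p = 0.0633), and collagens also without Cas9 3 (adjusted p = 0.112). The median of 1 Cas9 library had the sign opposite to the list for cholesterol synthesis (0.16 in Cas9 3), mesenchymal genes (0.11 in Cas9 2), collagens (0.05 in Cas9 2) and endothelial markers (-0.09 in Cas9 2). With an estimated correlation each of these 6 lists had an adjusted p = 0.789. Members with small p included Insig1 at 28.5 FPKM in Ctrl 3 and 14.6 ± 3.94 FPKM in Cas9 (SD, n = 3), Col18a1 at 66.5 and 47 ± 9 FPKM, Cldn5 at 6.74 and 16 ± 6.96 FPKM, Fasn at 50.8 and 40.3 ± 1.28 FPKM, and Dusp1 at 8.33 and 21.3 ± 7.7 FPKM. Some members with small p went against their list's direction. Twist1, of the mesenchymal list, stood at 18.3 and 22.9 ± 0.64 FPKM. Egr3, with the smallest p of the immediate early list, stood at 3.88 and 1.87 ± 0.44 FPKM. Plin2, of the fatty acid synthesis list, stood at 66.4 and 86.7 ± 8.25 FPKM. In all, 18 of 46 tested lists were called, 12 up and 6 down, and 0 with an estimated correlation. Adjusted over the list alone, 0 genes passed in the 17 called lists other than the interferon-stimulated one. The rotation test fry gave an unadjusted p of 0.00122 for interferon-stimulated genes and 0.0192 for MHC class I. For the other 16 called lists it lay above 0.05, from 0.0722 (lymphocyte markers) to 0.682 (cholesterol synthesis). The medians of the 12 lay at percentiles 99.4 to 100 of the random lists and those of the 6 at percentiles 0 to 3.71. The random lists carry no correlation between genes, so these percentiles add no support to the calls. Cholesterol synthesis, with the largest fry p, lay at percentile 0. Singling out another library in place of Ctrl 3 called 16 lists for Cas9 1, 14 for Cas9 2 and 16 for Cas9 3, so lists were called with each library. The median, mean and test differed in sign for 10 lists, of which 0 were called.

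**Figure D4:**
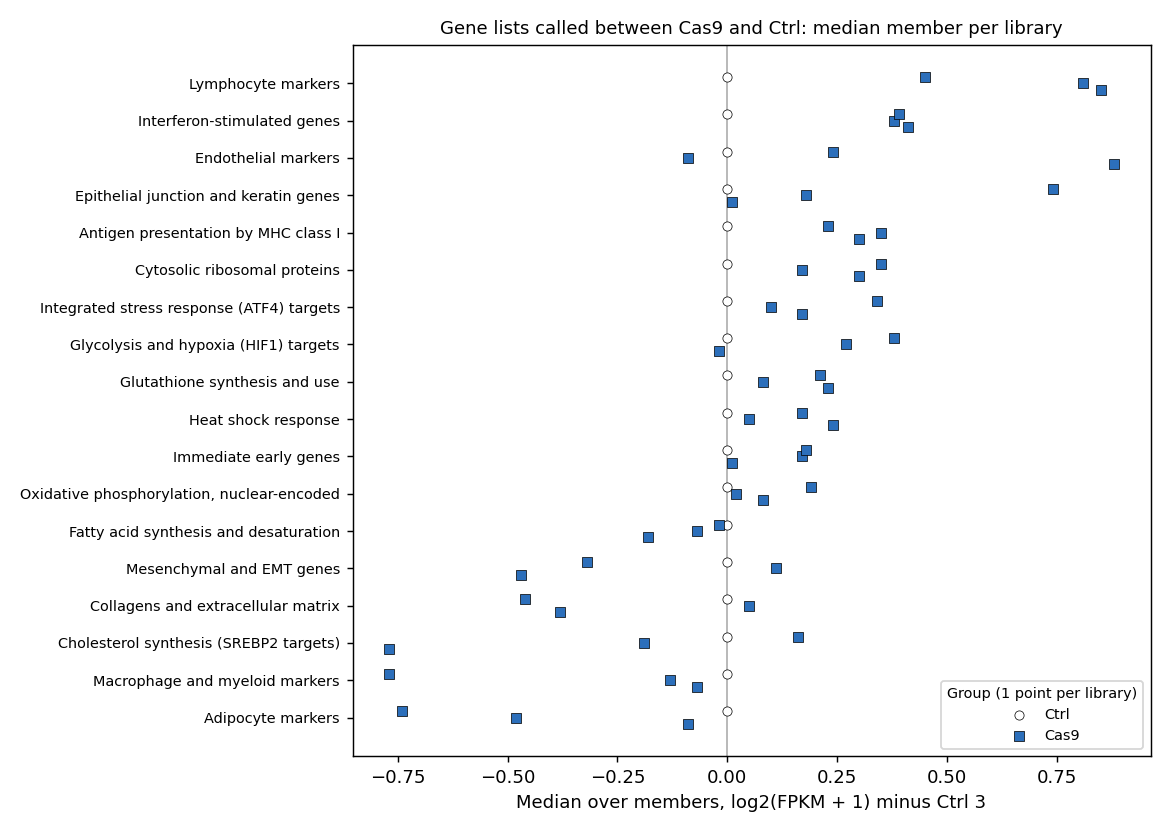
Median over the tested members of each of the 18 called lists, as log2(FPKM + 1) minus Ctrl 3, with 1 point per library (open circle Ctrl 3, at 0 by construction, and blue squares Cas9; replicates 1 to 3 are offset from bottom to top in each row). The interferon-stimulated list holds the 3 Cas9 libraries together at 0.38 to 0.41, while the epithelial list spreads from 0.01 to 0.74.

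Fold changes of GSH against WT and of Cas9 against Ctrl were nearly unrelated across 9535 genes tested in both tables, with Pearson's r of 0.0156 and Spearman's rho of 0.0461 across genes, which are not independent replicates. The sign was the same for 51.7% of these genes and for 51.8% of the 3850 that were called between GSH and WT. The Cas9 against Ctrl changes rest on 1 Ctrl library and on Cas9 libraries with a mean chi-square per gene of 56.8 to 118 between them. Such spread alone draws a correlation toward 0, so the low values do not show that the true changes are unrelated. MHC class I genes were called lower in GSH and higher in Cas9, and cytosolic ribosomal protein genes higher in both, all with the preset correlation. With an estimated one none of these 4 calls stayed (adjusted p = 0.343 and 0.736 for MHC class I, 0.688 and 0.789 for ribosomal proteins). The difference between the comparisons was not tested, since the tables were normalised separately.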

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

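The fits without or with only WT 3, GSH 2 and GSH 3, the term for them, voom, the rescaling without mitochondrially encoded genes and the GC and length trend were chosen after seeing the data. For GSH against WT, no gene passed at a fold threshold of 1.5 in limma (0 genes, 0 higher and 0 lower; 27 at an unadjusted p of 0.05). Leaving out each library in turn gave 2998 to 3671 genes (1663 to 2089 higher and 1335 to 1631 lower), lowest without WT 1. Without the 3 libraries with gland secretory genes 4 genes passed (3 higher, 1 lower), and with only those 3 libraries 0 (0 higher, 0 lower), where each fit rests on 3 libraries with 1 in one group, so low counts are expected. The 4 genes were Bpifa2 (log2 change 3.90), a salivary gene, with Rps12-ps9 (3.54) and Gm6576 (2.81), all higher in GSH 1, and a gene without a symbol (-1.49). The other settings gave 3086 (no filter) to 5187 genes (voom), and 3659 with the term for those libraries. None of the genes called with all libraries was called in the opposite direction under these settings, and 2 changed sign with the GC and length trend removed. With no filter, 8 named genes lost their call, 5 of them mitochondrially encoded. Scaling moved the median of all genes from 0.021 to -0.010 at most.

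The replicate numbers did not pair WT with GSH: same-numbered libraries deviated together with correlations of 0.48, -0.11 and 0.21, and the replicate block gave 3867 genes (2145 higher, 1722 lower) and 12 lists, without G2/M (adjusted p = 0.0725). No paired analysis was possible for Cas9 against Ctrl because the groups share 1 replicate number with values. The estimated correlation left 0 lists in both comparisons, and leaving out each library gave 10 to 13 lists for GSH against WT and 15 to 26 for Cas9 against Ctrl.

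For Cas9 against Ctrl, the spread pooled over all 10 libraries gave 43 genes (30 higher, 13 lower); the other settings gave 0 genes, and 0 when each Cas9 library was left out. The pooled spread assumed that the libraries of both tables vary alike, which the pairs of libraries did not bear out. The correlation between the comparisons was 0.0179 among genes with 50 or more reads and 0.0166 with relative log expression scaling. DESeq2 was planned and not run, as the files hold FPKM. Weakly expressed genes rest on fewer reads than others, so their values are less precise.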

Other observations

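The families, the marker lists and the tests of other splits, of the gland genes' grouping, of poly(A) selection and of leukocytes and lymphocytes were chosen after their results were seen. The tests on mitochondrial reads, GC content and length, the term for 3 libraries and nasal genes were written before their results, though after the calls had been explored, and the count without WT 3, GSH 2 and GSH 3 was known when that term was chosen.

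Grouping tested genes by the stem of their symbols gave 106 families of 10 or more genes for GSH against WT. All 14 tested Psmd genes, subunits of the proteasome's regulatory particle, rose in GSH (median log2 change 0.19, camera adjusted p = 0.000151, adjusted p = 0.557 with an estimated correlation). Of 52 Eif genes, translation initiation factors, 28 rose and 1 fell (adjusted p = 1.27e-05, adjusted p = 0.557 with an estimated correlation). Srsf genes, which encode splicing factors, went the other way, with 6 of 10 lower and 1 higher (median -0.22, adjusted p = 0.015, adjusted p = 0.557 with an estimated correlation), and 70 of 257 zinc-finger Zfp genes fell while 19 rose (adjusted p = 0.000151, adjusted p = 0.557 with an estimated correlation). Trp53 itself, named after its value was seen, fell from 35.2 ± 0.48 to 25.4 ± 0.332 FPKM (SD, n = 3 each; log2 change -0.46, adjusted p = 0.00112), while the list of its targets was not called.

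Some genes passed between Cas9 and Ctrl 3 only with a pooled spread, whose assumption of like variation did not hold, so these calls are not relied on. The values of Pdcd1, Gzme and Padi1, which were among them, describe these libraries only. The T-cell checkpoint receptor gene Pdcd1 stood at 1.06 FPKM in Ctrl 3 and 3.86, 4.34 and 3.14 FPKM in Cas9 1 to 3, while Gzme stood at 36 and 19.4, 16.7 and 17.5 FPKM and Padi1 at 10.3 and 4.51, 5.08 and 4.81 FPKM. Cytotoxic granule genes together took 230 RPM in Ctrl 3, 245, 76.1 and 145 RPM in Cas9 1 to 3, and 1.55 to 3.02 RPM in the WT and GSH libraries, whose table was normalised separately and lists 8 of these genes against 14. Skeletal muscle genes took 19.4 RPM in Ctrl 3 and 55.3, 37 and 19.7 RPM in Cas9 1 to 3. They took 320 RPM in WT 2 and 106 to 134 RPM in the other WT and GSH libraries. Haemoglobin genes took 40.9 to 184 RPM in the Ctrl and Cas9 libraries and 5.36 to 53.2 RPM in the WT and GSH libraries, where cornified epidermis genes took 35.3 to 69.2 RPM. On the first principal component (63% of the variance) Cas9 3 stood at 36.2. Ctrl 3, at -11.3, lay between Cas9 1 (-16) and Cas9 2 (-8.88), so this component did not separate the groups. Krtdap and Calm4, genes of cornifying keratinocytes, stood at 59.8 and 53.4 FPKM in Cas9 3 and were listed at 0 in Ctrl 3, Cas9 1 and Cas9 2.

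Many genes passed between GSH and WT at small fold changes. After FPKM were rescaled without mitochondrially encoded genes, 85.8% of the 4547 genes stayed past the threshold in the same direction. That rescaling moved the median log2 change of all genes only from 0.021 to -0.010. Called genes had a median absolute change of 0.22, so most calls could hardly end and this check decides nothing. With a GC and length trend removed, 91.7% of 4531 stayed past the threshold in the same direction. With a term for WT 3, GSH 2 and GSH 3, 78.1% did. These shares argue against the trend, and against the difference that the term stands for, as the whole cause. The greater depth of GSH 1 was tested first and then replaced by that term, with 90.3% kept after thinning to the smallest library, and the real split gave 4547 genes and the highest of the other 9 splits gave 17, and for lists 13 and 10, with 1 of 10 splits at the real count in each case, and 10 splits are too few for a share under 0.05. A difference in poly(A) selection stays open, since the 2 tested replication-dependent histone genes rose in every GSH library (median 0.38) but are few and may follow the cell cycle, and the genotype named in the labels stays open, untested.

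Secretory genes of nasal and other glands appeared in libraries labelled as cultured cells. Odorant-binding protein Obp1a had 2151, 2405 and 893 reads in WT 3, GSH 2 and GSH 3 and 16 to 19 in the other 3 libraries, and the secretory families together had 10.8 times the RPM in WT 3 as in GSH 1, which argues against the grouping as their source. Whole nasal mucosa as one source is argued against as well, since 1 of 15 detected mucosa genes was higher in each of those 3 libraries than in the others, and Bpifa1 had 139 reads in WT 2 and 11 in WT 3. Salivary gland genes were highest in GSH 1 (51.8 RPM against 13.9 to 21.9 RPM in the other 5) and nasal mucosa genes in GSH 3 (65.4 RPM against 14.4 to 47.1 RPM), while in the Ctrl and Cas9 libraries they took 7.51 to 14.8 and 3.86 to 7.94 RPM and the secretory families 0.433 to 2.55 RPM, over 5, 13 and 20 listed genes against 12, 16 and 22. Reads misassigned from other libraries of a sequencing run, or a gland without its surrounding mucosa, may account for them and were not tested.

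Interferon-stimulated genes were higher in Cas9 than in Ctrl 3 in a list call that an estimated correlation ended (adjusted p = 0.184). For more leukocytes of every kind, the lymphocyte list median was set against the macrophage list median. It was higher in each Cas9 library, by 0.92 to 1.22 (SD 0.17). With Ctrl 3 taken to vary like the Cas9 libraries, the SD was 0.24. This criterion was set after the macrophage medians (highest -0.07) had been seen to miss an earlier one, so it decides nothing. No Cas9 library had a macrophage median above Ctrl 3. Ptprc was not higher in any Cas9 library either, at 124 RPM in Ctrl 3 and 108, 123 and 92.8 RPM in Cas9 1 to 3. With 1 Ctrl library the explanation still stays open. More lymphocytes stays open, as their list median was at least 0.45 above Ctrl 3 in each Cas9 library, and Ifng stood at 0.443 FPKM in Ctrl 3 and 0.624, 0.324 and 0.191 FPKM in Cas9 1 to 3. When each of the 4 libraries was singled out in turn, Ctrl 3 gave the list the smallest camera p (2.97e-37, 1 of 4 libraries) and the next was 7.68e-07 for Cas9 2, and 4 libraries are too few for a share under 0.05. The Cas9 genotype stays open and untested, since with 1 Ctrl library it cannot be told apart from a trait of that library, and with Ptprc at 92.8 to 124 RPM the values may describe mixtures of cells.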
